A study of Mus musculus with 12 samples.

How the data were processed

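RNA was measured in 12 libraries of cultured mouse hematopoietic stem cells: long-term (LT-HSC) and short-term (ST-HSC) cells sorted from bone marrow, each grown for 2 days with or without 1 mM nicotinamide riboside (NR), renewed after 24 h, with 3 samples per group. Per the labels' protocols, cells grew in Stemline II medium with 100 ng/ml SCF and 2 ng/ml Flt3 ligand, and libraries were made from 2.5 ng RNA by SMART-seq v4 amplification followed by Nextera XT tagmentation. The deposited values are read counts per Ensembl gene: per the submitters' processing notes reads were checked with FastQC 0.11.2, aligned with STAR 2.5.0b and counted with HTSeq 0.6.1. The genome build, the annotation release, the strand setting and any read filter are not given in the sources used here. Each library is 1 column of 1 table, and 0 columns were not used.

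The table held 53465 genes, of which 53274 had a symbol in the GENCODE M21 table, 80 had a symbol shared with another identifier and 7079 had 0 counts in all libraries. Counts that HTSeq assigned to no gene were kept out of library sizes and tests: reads in no annotated feature made up 8.69% to 28.5% of reads and ambiguous reads 3.30% to 4.38%. Gene counts per library ran from 24.6 M to 35.5 M (median 31.7 M), and 21881 to 39290 genes had counts in a library. The biological coefficient of variation was 0.402, with 8 residual degrees of freedom. No pair of libraries in a group was a duplicate: the chi-square per degree of freedom between replicates ran from 6.30 to 37.2.

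Groups were taken from the labels. The test was edgeR 4.0.16 (quasi-likelihood fit and test, two-sided) with TMM factors on all 12 samples and 4 group means, after filterByExpr by group (minimum count 10, minimum total 15), which kept 19830 genes. The comparisons were NR against control in LT-HSCs, in ST-HSCs and averaged over both; the difference of these effects; and LT-HSCs against ST-HSCs in control culture and with NR. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. Gene lists were written before the files were opened, and the 39 lists with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison; a second p used a correlation estimated for each list. Adjusted over the list alone means that the edgeR p-values of a list's genes were adjusted among themselves. Standard errors are those of the log2 change, and CPM values are given with the SD.

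The rule for named genes was written before the data were examined, as were the lists, the tests and most of the other settings listed below. It takes, from genes past adjusted p 0.05 with a mean of at least 5 CPM and replicates that do not overlap, the 10 largest rises and falls of each comparison, leaving out predicted genes, clones and pseudogenes. It adds up to 4 members with the smallest p in the direction of each called list, the 5 genes with the smallest p where under 5 pass, and NAD metabolism, sirtuin and sort marker genes chosen beforehand.

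Other settings chosen beforehand were relative log expression and upper-quartile factors, DESeq2 1.42.0, limma-voom with sample quality weights, no filter, a stricter filter (mean of at least 5 CPM), a fit of only the 2 groups compared, the sample number as a block, each library left out in turn, and the fry test for lists. Added after seeing the data were the logit of the unassigned share as a covariate, leaving out the 2 libraries with more than 20% of reads in no feature, exchanges of NR labels only within samples of the same cell type and number, and fits on fewer libraries with the genes tested kept as in the full fit. The last was added after seeing that the numbers of called genes dropped when the filter was applied again. A smaller group lets more low-count genes through the filter. Whether these genes alone made the numbers drop was not tested.

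The edgeR and camera steps were tested on simulated data with 200 changed genes among 19830. In LT-HSCs 26.9%, 46.3% and 66.7% of genes changed 1.5-, 2- and 4-fold were recovered, in ST-HSCs 31.3%, 38.8% and 62.1%, for the averaged effect 47.8%, 52.2% and 69.7%, and for the difference of effects 20.9%, 40.3% and 59.1%. For LT-HSCs against ST-HSCs these were 41.8%, 53.7% and 51.5% in control culture and 34.3%, 49.3% and 72.7% with NR. False calls made up 1.74% to 7.37% of calls. A simulated list of 30 genes moved 1.25-fold was called in each comparison, with 0 other lists. The simulated genes varied independently of each other. In the real lists the estimated correlation ran from -0.0052 (NAD metabolism) to 0.832 (cytosolic ribosomal proteins). The simulation therefore cannot show how often lists of correlated genes are called falsely. Its rises and falls were drawn at random, and the other genes had the same mean in all groups. The low-count filter was not applied to the simulated counts, and differences in unassigned reads were not simulated. In the real data 1975 to 4752 genes were called with NR, mostly lower. The recovery and false-call rates may therefore not hold for them. Computation used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.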

Results

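RNA of mouse hematopoietic stem cells (HSCs) from bone marrow was sequenced in bulk after 2 days of culture with or without 1 mM nicotinamide riboside (NR), a form of vitamin B3 from which cells make nicotinamide adenine dinucleotide (NAD). Both sorted populations were lineage-negative and positive for Kit, Sca1 and CD150 and lacked CD48. Long-term HSCs (LT-HSCs) also lacked CD34, while short-term HSCs (ST-HSCs) carried it. The 12 libraries form 4 groups of 3 samples: control LT-HSCs, NR LT-HSCs, control ST-HSCs and NR ST-HSCs. No label says whether the samples of a group come from separate mice or cultures. The p-values therefore measure only the spread between these samples, which may be technical. Between 24.6 M and 35.5 M counts were assigned to genes per library.

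The libraries differed in the share of reads that fell in no annotated gene, from 8.69% to 28.5% with a median of 12.1%. NR LT-HSC sample 3 (28.5%) and NR ST-HSC sample 3 (26.2%) lay above all other libraries, whose highest value was 17.0%. Olfactory receptor genes were taken to be largely silent in these cells, which was not tested. They took more reads in libraries with a higher share (Pearson r = 0.996 and Spearman rho = 0.979, n = 12, permutation p = 2e-05 for each). This p is the smallest that 100000 permutations can give, and 1 relation was computed. Without these 2 libraries, which are also the farthest from the median, r was 0.986; it was 0.988 within the 6 control libraries and 1.000 within the 6 NR libraries. The first principal component of the log2 CPM (gene counts scaled by library size) held 56.4% of the variance. It largely followed the share of reads in no annotated gene. NR ST-HSC sample 1 lay at -98.7 (9.17%), control ST-HSC sample 3 at 58.7 (16.5%) and NR LT-HSC sample 3 at 131 (28.5%). The order was not exact, since control LT-HSC sample 2, with the lowest share (8.69%), lay at -58.8. LT-HSCs and ST-HSCs separated on the second component (10.3%), and NR and control on the third (8.72%).

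**Figure D1:**
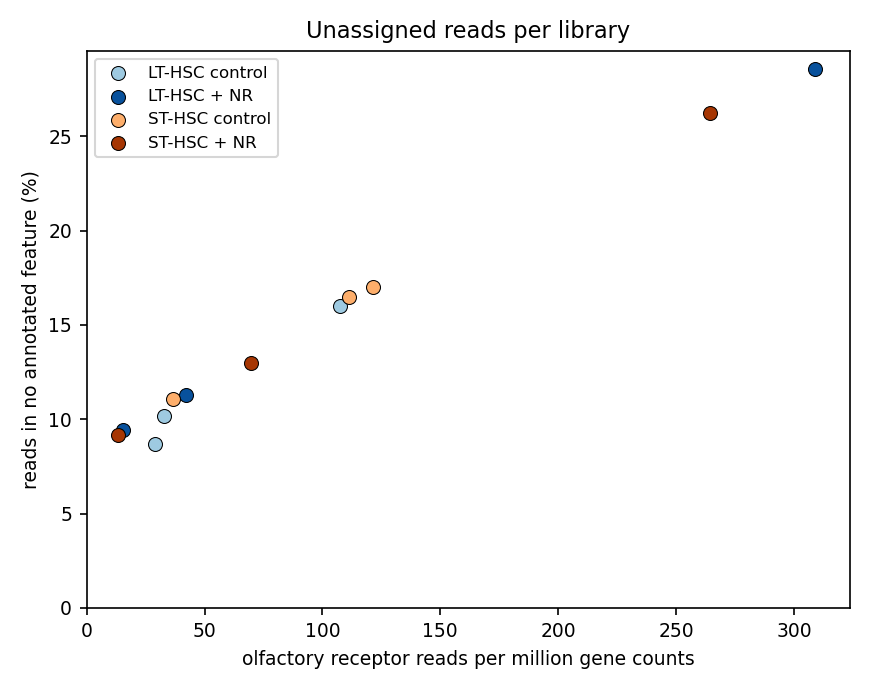
Reads in olfactory receptor genes per M gene counts (x axis) against the percent of reads in no annotated gene (y axis), with 1 point for each of the 12 libraries coloured by group. The 2 libraries at the upper right, NR LT-HSC sample 3 and NR ST-HSC sample 3, hold 28.5% and 26.2% of reads in no annotated gene.

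The comparison of NR with control LT-HSCs asked which transcripts change in the cells with the longest repopulating capacity. With NR, Cdkn1a (ENSMUSG00000023067), which encodes the cell cycle inhibitor p21, rose from 30.5 ± 0.49 to 82.5 ± 13.7 CPM (mean ± SD, n = 3), a log2 change of 1.44 ± 0.11 (SE; edgeR adjusted p = 1.7e-05). Phlda3 (ENSMUSG00000041801), a p53-induced inhibitor of Akt signalling, rose by 1.77 ± 0.15, and Eda2r (ENSMUSG00000034457), a death receptor, by 2.25 ± 0.18. Trp53inp1 rose by 2.02 ± 0.14, the cytokine gene Gdf15 by 1.78 ± 0.19 and the long noncoding Trp53cor1 by 1.60 ± 0.16. Other large rises were those of the iron exporter gene Slc40a1 (2.39 ± 0.28), the heme oxygenase gene Hmox1 (2.18 ± 0.37), Ddit4l (2.15 ± 0.20) and Tnfsf4 (1.90 ± 0.18). Large falls on the log2 scale were those of Hsd17b1 (-2.47 ± 0.31), the proline synthesis gene Pycr1 (-2.20 ± 0.31), and the transcription factor gene Etv4 (-2.01 ± 0.19). Smaller falls were those of the integrin gene Itgal (-1.58 ± 0.15), Vash2 (-1.48 ± 0.21), Gdf3 (-1.48 ± 0.13) and Pnck (-1.47 ± 0.20).

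Of 28 p53 target genes, 16 rose in LT-HSCs, 0 fell and 12 did not pass; adjusted over the list alone, 19 rose and 1 fell. Their median log2 change was 0.64 (list test adjusted p = 4.3e-17; adjusted p = 0.115 with an estimated correlation). With the low-count filter applied again, 10 members rose without control sample 1 and 10 without NR sample 1. The integrated stress response, in which the factor ATF4 drives amino acid synthesis and transport, fell: 21 of 33 members were lower, 2 were higher (Sesn2 and Gdf15, both also p53 targets, named after their values were seen) and 10 did not pass. With p adjusted over the list alone 23 were lower and 4 higher (median -0.72, adjusted p = 1.2e-11; adjusted p = 0.287 with an estimated correlation). Without control sample 2, 13 of its members were lower. The serine synthesis genes Phgdh and Psat1 fell by 1.02 ± 0.06 and 0.77 ± 0.06, the folate cycle genes Shmt2 and Mthfd2 by 0.91 ± 0.07 and 1.14 ± 0.13, and the transfer RNA ligase gene Gars by 0.67 ± 0.06. NRF2 and antioxidant genes rose in 12 cases and fell in 4 of 33, against 15 and 6 adjusted over the list alone (median 0.27, adjusted p = 8.5e-05; adjusted p = 0.513 with an estimated correlation). Without control sample 2 only 6 of them rose, and without NR sample 2 only 7. No member fell without any 1 of the 6 libraries. Among them Nqo1 rose by 1.24 ± 0.17, the sulfiredoxin gene Srxn1 by 0.94 ± 0.10 and the ferritin gene Ftl1 by 0.73 ± 0.10.

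In all, 472 genes were higher and 1503 lower with NR in LT-HSCs. With any 1 of the 6 libraries left out and the low-count filter applied again, 78 to 382 were higher and 101 to 455 lower. With the same genes tested these numbers were 242 to 464 and 835 to 1082. The higher share, 23.9%, was 37.4% with relative log expression factors and 35.3% with upper-quartile factors. It was 40.1% with DESeq2, which also changes the test. Without the 2 libraries richest in unassigned reads it was 51.0% with the filter applied again and 37.3% with the same genes tested.

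The same comparison in ST-HSCs again gave rises of p53 target genes. Cdkn1a went from 20.5 ± 0.66 to 135 ± 12.2 CPM (mean ± SD, n = 3), a log2 rise of 2.72 ± 0.11 (SE; edgeR adjusted p = 7.8e-08), and Phlda3 from 6.15 ± 0.67 to 62.4 ± 12.3 CPM, a rise of 3.35 ± 0.16. Ddit4l rose by 3.90 ± 0.23, Eda2r by 3.34 ± 0.19, Tnfsf4 by 3.17 ± 0.19 and Slc40a1 by 2.87 ± 0.31. Trp53inp1 rose by 2.82 ± 0.14, Dglucy by 2.81 ± 0.25, Gdf15 by 2.78 ± 0.20 and Hmox1 by 2.61 ± 0.39. On the other side, the branched-chain aminotransferase gene Bcat1 fell by 3.41 ± 0.71 and the glutathione-degrading Chac1 by 3.27 ± 0.50. Hsd17b1 fell by 2.89 ± 0.31, Pycr1 by 2.87 ± 0.32, the amino acid transporter gene Slc1a4 by 2.64 ± 0.33 and the asparagine synthetase gene Asns by 2.05 ± 0.17. Vwf, which encodes von Willebrand factor, fell by 2.23 ± 0.17, Etv4 by 2.25 ± 0.19, Adam11 by 2.16 ± 0.44 and Serpinf1 by 2.08 ± 0.14.

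**Figure D2:**
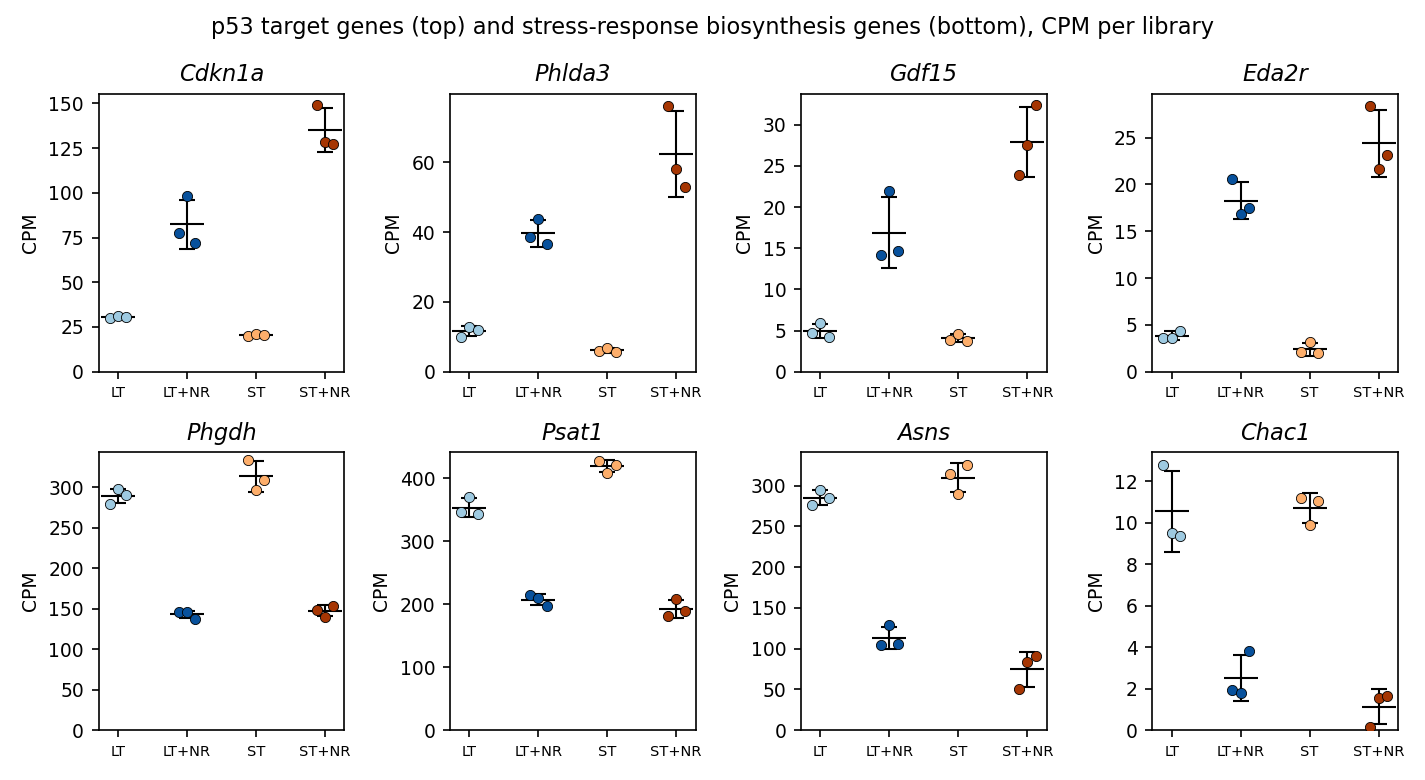
CPM per library (y axis) of the p53 target genes Cdkn1a, Phlda3, Gdf15 and Eda2r (top) and the integrated stress response genes Phgdh, Psat1, Asns and Chac1 (bottom) in the 4 groups (x axis); points are libraries, lines means and bars SD. Cdkn1a averages 30.5 and 82.5 CPM in control and NR LT-HSCs and 20.5 and 135 CPM in ST-HSCs.

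Of the 28 p53 target genes, 21 rose in ST-HSCs, 0 fell and 7 did not pass, with 24 higher and 1 lower adjusted over the list alone (median 1.11, adjusted p = 1.2e-23). This was the only list of NR against control in ST-HSCs that also passed with an estimated correlation (adjusted p = 0.0459). Besides the genes above, the apoptosis genes Bbc3, Fas and Bax rose by 1.56 ± 0.13, 1.64 ± 0.17 and 1.05 ± 0.13. Integrated stress response genes fell in 23 cases and rose in 3 of 33, or 24 and 4 adjusted over the list alone (median -1.09, adjusted p = 5.7e-12; adjusted p = 0.224 with an estimated correlation). Phgdh fell by 1.09 ± 0.06, Psat1 by 1.12 ± 0.06, Shmt2 by 1.11 ± 0.07 and Mthfd2 by 1.66 ± 0.13. NRF2 and antioxidant genes rose in 19 cases and fell in 3 of 33, or 21 and 3 adjusted over the list alone (median 0.40, adjusted p = 5.5e-10; adjusted p = 0.327 with an estimated correlation). Of these, Gstm1 rose by 1.58 ± 0.13, Srxn1 by 1.23 ± 0.10, Ftl1 by 1.11 ± 0.11 and Taldo1 by 0.87 ± 0.09.

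Lists of inflammatory and degradative genes passed the camera test with the preset correlation with NR in both cell types. In LT-HSCs none of them passed the directional fry test. In ST-HSCs NF-kB and inflammatory response genes were higher in 10 of 23 cases and lower in 1, the same as adjusted over the list alone (median 0.50, adjusted p = 4.6e-07; adjusted p = 0.184 with an estimated correlation). Interferon response genes were higher in 17 and lower in 2 of 47, or 24 and 3 adjusted over the list alone (median 0.44, adjusted p = 2.2e-08; adjusted p = 0.327 with an estimated correlation). The chemokine genes Ccl3 and Ccl4 rose by 3.26 ± 0.39 and 2.19 ± 0.21, the signalling adaptor gene Traf1 by 1.61 ± 0.14, Zbp1 by 1.71 ± 0.32 and Irf1 by 0.65 ± 0.09. Lysosome genes were higher in 14 and lower in 2 of 28, or 17 and 2 adjusted over the list alone (adjusted p = 5.7e-08; adjusted p = 0.257 with an estimated correlation). Mitophagy and autophagy genes were higher in 15 and lower in 2 of 35, or 17 and 2 (adjusted p = 2.1e-05; adjusted p = 0.327 with an estimated correlation). Psap rose by 0.52 ± 0.06, the protease gene Ctsd by 0.53 ± 0.07, the autophagy receptor gene Sqstm1 by 1.11 ± 0.07 and Gabarapl1 by 0.72 ± 0.08. With the filter applied again, the interferon list had 11 rises without control sample 2, 11 without control sample 3, 9 without NR sample 1 and 11 without NR sample 2. The lysosome list then had 7, 7, 5 and 6. Mitophagy genes rose in 8 cases without control sample 3, 7 without NR sample 1 and 6 without NR sample 2.

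In LT-HSCs these 4 lists had fewer members called higher. The directional fry test gave adjusted p = 0.0791 for NF-kB, 0.3 for interferon, 0.3 for lysosome and 0.061 for mitophagy genes. With the sample number as a block the NF-kB and lysosome calls ended (camera adjusted p = 0.0626 and 0.104). NF-kB genes were higher in 4 and lower in 0 cases, or 5 and 0 adjusted over the list alone (adjusted p = 0.0324; adjusted p = 0.364 with an estimated correlation). Interferon response genes were higher in 6 and lower in 3, or 10 and 4 (adjusted p = 0.00176; adjusted p = 0.542 with an estimated correlation). Lysosome genes were higher in 5 and lower in 2, or 9 and 3 (adjusted p = 0.0476; adjusted p = 0.639 with an estimated correlation). Mitophagy genes were higher in 7 and lower in 1, or 11 and 2 (adjusted p = 0.000546; adjusted p = 0.407 with an estimated correlation). With any 1 of the 6 libraries left out, 1 to 3, 0 to 7, 0 to 5 and 1 to 6 members were higher with the filter applied again, and 2 to 4, 1 to 8, 1 to 5 and 5 to 8 with the same genes tested. With the filter applied again the NF-kB call ended without control sample 1 or 3 or NR sample 1 or 2, and the interferon call without control sample 3 or NR sample 1. The lysosome call ended without control sample 3 or NR sample 1 or 2, and the mitophagy call without NR sample 1.

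Of the marker lists of other blood cells 2 passed in ST-HSCs, while those of erythroid, myeloid, mast and lymphoid cells did not (adjusted p = 0.398 to 0.895). Monocyte, macrophage and dendritic markers were higher in 4 and lower in 0 of 15, the same as adjusted over the list alone (median 0.45, adjusted p = 0.00518; adjusted p = 0.224 with an estimated correlation). Cd68 rose by 2.17 ± 0.21, Tyrobp by 1.64 ± 0.23 and Fcer1g by 0.96 ± 0.09. The list's call ended without control sample 1, and without the 2 libraries richest in unassigned reads when the filter was applied again. Megakaryocyte and platelet genes fell in 6 cases and rose in 2 of 24, or 10 and 2 adjusted over the list alone (median -0.17, adjusted p = 0.0466; adjusted p = 0.573 with an estimated correlation), among them Itga2b (-0.76 ± 0.11). The megakaryocyte call ended without control sample 1 or 2, without NR sample 3 and with the stricter filter. Genes of the G2 phase and mitosis fell in 11 cases and rose in 1 of 38, or 20 and 1 adjusted over the list alone (median -0.32, adjusted p = 2.1e-05; adjusted p = 0.541 with an estimated correlation). That number rested on single libraries. With the same genes tested it was 0 without NR sample 3 and at most 33 over the 6 libraries left out in turn, all of which moved it by over 1.5 times.

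In all, 1155 genes were higher and 2193 lower with NR in ST-HSCs. With any 1 of the 6 libraries left out and the filter applied again, 556 to 1326 were higher and 398 to 759 lower. They were 833 to 1375 and 1010 to 2130 with the same genes tested. The higher share of 34.5% became 51.7% with relative log expression factors, 47.9% with upper-quartile factors and 50.7% with DESeq2. Leaving out the 2 libraries richest in unassigned reads gave 61.2% with the filter applied again and 55.7% with the same genes tested.

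Averaged over both cell types, 6 samples against 6, NR went with lower transcripts of protein synthesis and of mitochondrial energy metabolism. The median averaged change was -0.068 over the 10473 genes at 5 CPM or more and 0.313 over the 9357 below. With the stricter filter the median over the genes kept was 0.0044, so the size of small falls depends on the scaling. The polyamine synthesis gene Srm fell by 0.84 ± 0.05, the nucleolar genes Ncl and Npm1 by 0.52 ± 0.04 and 0.55 ± 0.04 and the lactate dehydrogenase gene Ldha by 0.61 ± 0.05. Of 36 ribosome biogenesis and MYC target genes 34 fell and 0 rose, or 35 and 0 adjusted over the list alone (median -0.41, adjusted p = 3.8e-21; adjusted p = 0.191 with an estimated correlation). Of these, 32 fell in LT-HSCs and 27 in ST-HSCs. Cytosolic ribosomal protein genes fell in 67 of 75 cases, 69 adjusted over the list alone (median -0.27; adjusted p = 4.4e-20; adjusted p = 0.282 with an estimated correlation). In LT-HSCs 58 were lower and in ST-HSCs 41. Among them Rpl5 fell by 0.47 ± 0.05. Among 30 genes of nucleotide, one-carbon and methionine metabolism 22 fell, 25 adjusted over the list alone (median -0.28, adjusted p = 1.1e-11; adjusted p = 0.241 with an estimated correlation), with Mthfd2 at -1.40 ± 0.09 and Shmt1 at -0.66 ± 0.04.

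The nuclear genes of respiratory chain complexes II to V fell in 37 of 39 cases, 38 adjusted over the list alone (median -0.33, adjusted p = 8.5e-18; adjusted p = 0.281 with an estimated correlation), such as Uqcrq (-0.53 ± 0.05) and Atp5b (-0.44 ± 0.05). Complex I genes fell in 32 of 37 cases, 34 adjusted over the list alone (adjusted p = 3.3e-13). Mitochondrial ribosome and import genes fell in 33 of 41, 38 adjusted over the list alone (adjusted p = 3.8e-15), and tricarboxylic acid cycle genes in 19 of 22, 22 adjusted over the list alone (adjusted p = 3.7e-10). None of these rose, and each had adjusted p = 0.281 with an estimated correlation. Examples are Ndufa10 (-0.45 ± 0.06), Mrps28 (-0.72 ± 0.06), Suclg2 (-0.58 ± 0.05) and Idh2 (-0.47 ± 0.05). Of the 8 tested genes that mitochondrial DNA encodes 6 fell, 8 adjusted over the list alone (adjusted p = 7e-05; adjusted p = 0.281 with an estimated correlation), with mt-Nd1 at -0.42 ± 0.05. The share of counts from all mitochondrial genes, ribosomal RNA included, went from 0.75 ± 0.04% to 0.67 ± 0.01% in LT-HSCs but from 0.69 ± 0.02% to 0.76 ± 0.07% in ST-HSCs (mean ± SD, n = 3, not tested). Mitochondrial chaperones fell with them. In all, 11 of the 16 genes of the mitochondrial unfolded protein response fell, 11 also adjusted over the list alone (adjusted p = 3.9e-05; adjusted p = 0.281 with an estimated correlation), among them Hspd1 (-0.57 ± 0.04) and Hspa9 (-0.51 ± 0.04). Genes of the G1/S transition and DNA replication fell in 19 of 33 cases, 22 adjusted over the list alone (adjusted p = 3.8e-06; adjusted p = 0.281 with an estimated correlation), as in Mcm7 (-0.41 ± 0.04).

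Within 1 cell type fewer of these single genes were called when the filter was applied again. In LT-HSCs, with any 1 of the 6 libraries left out and the filter applied again, 0 to 13 ribosomal protein genes, 2 to 18 ribosome biogenesis genes, 0 to 3 complex I genes and 0 to 11 genes of complexes II to V were lower. In ST-HSCs these numbers were 0 to 7, 10 to 15, 0 to 1 and 1 to 8. With the same genes tested 23 to 47, 29 to 31, 5 to 19 and 16 to 29 genes were lower in LT-HSCs, and 11 to 49, 17 to 28, 2 to 20 and 13 to 28 in ST-HSCs. For the averaged effect 17 to 37, 28 to 30, 10 to 25 and 16 to 33 genes were lower. With the same genes tested they were 54 to 67, 32 to 34, 24 to 32 and 34 to 38. These falls also shrank without the 2 libraries richest in unassigned reads. In ST-HSCs 10 ribosomal protein genes were then lower and 2 higher (median -0.07), and 2 complex I genes lower (median -0.13).

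The averaged effect held the stress genes of both cell types. Of the p53 targets 22 rose and 1 fell, the same adjusted over the list alone (median 0.85, adjusted p = 3.5e-20; adjusted p = 0.0781 with an estimated correlation), with Cdkn1a at 2.08 ± 0.08 (adjusted p = 2e-08) and higher in 6 of 6 NR samples than in each control of the same cell type. The integrated stress response fell in 23 cases and rose in 4, or 27 and 5 adjusted over the list alone (median -0.94, adjusted p = 2.1e-11; adjusted p = 0.241 with an estimated correlation). NRF2 and antioxidant genes rose in 20 and fell in 6, or 21 and 7 (adjusted p = 2.7e-07; adjusted p = 0.287 with an estimated correlation). Interferon response genes rose in 23 and fell in 4, or 24 and 4 (adjusted p = 9.8e-07; adjusted p = 0.282 with an estimated correlation). Chaperones of the endoplasmic reticulum fell in 14 of 22 cases, or 14 lower and 1 higher adjusted over the list alone (adjusted p = 1.8e-05; adjusted p = 0.281 with an estimated correlation), among them Hspa5 (-0.50 ± 0.05) and Calr (-0.49 ± 0.04).

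Averaged over both cell types 1563 genes were higher and 3189 lower, a higher share of 32.9% that became 48.5% with relative log expression factors, 46.0% with upper-quartile factors and 48.7% with DESeq2. Without the 2 libraries richest in unassigned reads it was 57.4% with the filter applied again and 49.4% with the same genes tested. With any 1 of the 12 libraries left out, the filter applied again, 1265 to 1764 genes were lower. LT-HSCs and ST-HSCs shared 381 genes higher and 1170 lower with NR, where 27.5 and 166 would be shared by independent calls, and 0 genes were called in opposite directions in the edgeR test. The expected numbers are too low, because most calls lay among genes at 5 CPM or more. These were 1906 of 1975 calls in LT-HSCs and 3095 of 3348 in ST-HSCs. Of the 1975 genes called in LT-HSCs 99.0% had the same sign in ST-HSCs (r = 0.912 across genes, which are not independent replicates). Over all 19830 genes tested 72.2% had the same sign (r = 0.354). These values come from the fit of all 12 libraries, where NR sample 3 of each cell type held the most unassigned reads (28.5% and 26.2%). A shift of scaling or background common to both cell types could add to the agreement, which was not tested.

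**Figure D3:**
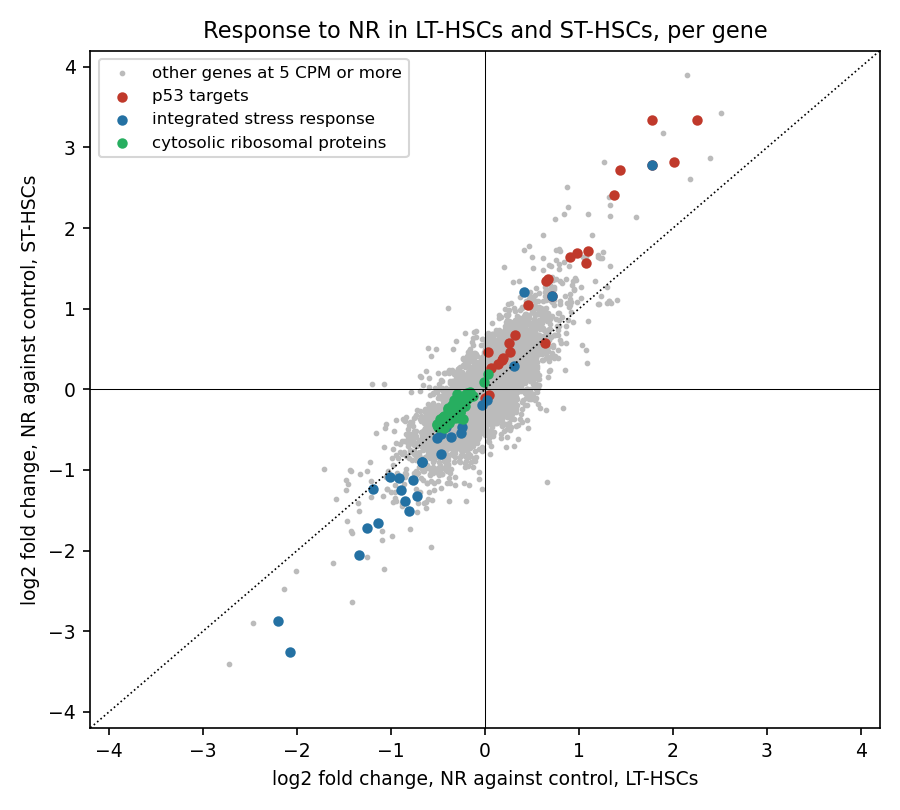
Log2 change with NR in LT-HSCs (x axis) against that in ST-HSCs (y axis) for genes with a mean of at least 5 CPM, 1 point a gene, with p53 targets in red, integrated stress response genes in blue and cytosolic ribosomal protein genes in green; the dotted line marks equal changes. Cdkn1a (1.44 and 2.72) and Phlda3 (1.77 and 3.35) lie above the line, and Phgdh (-1.02 and -1.09) near it.

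**Figure D4:**
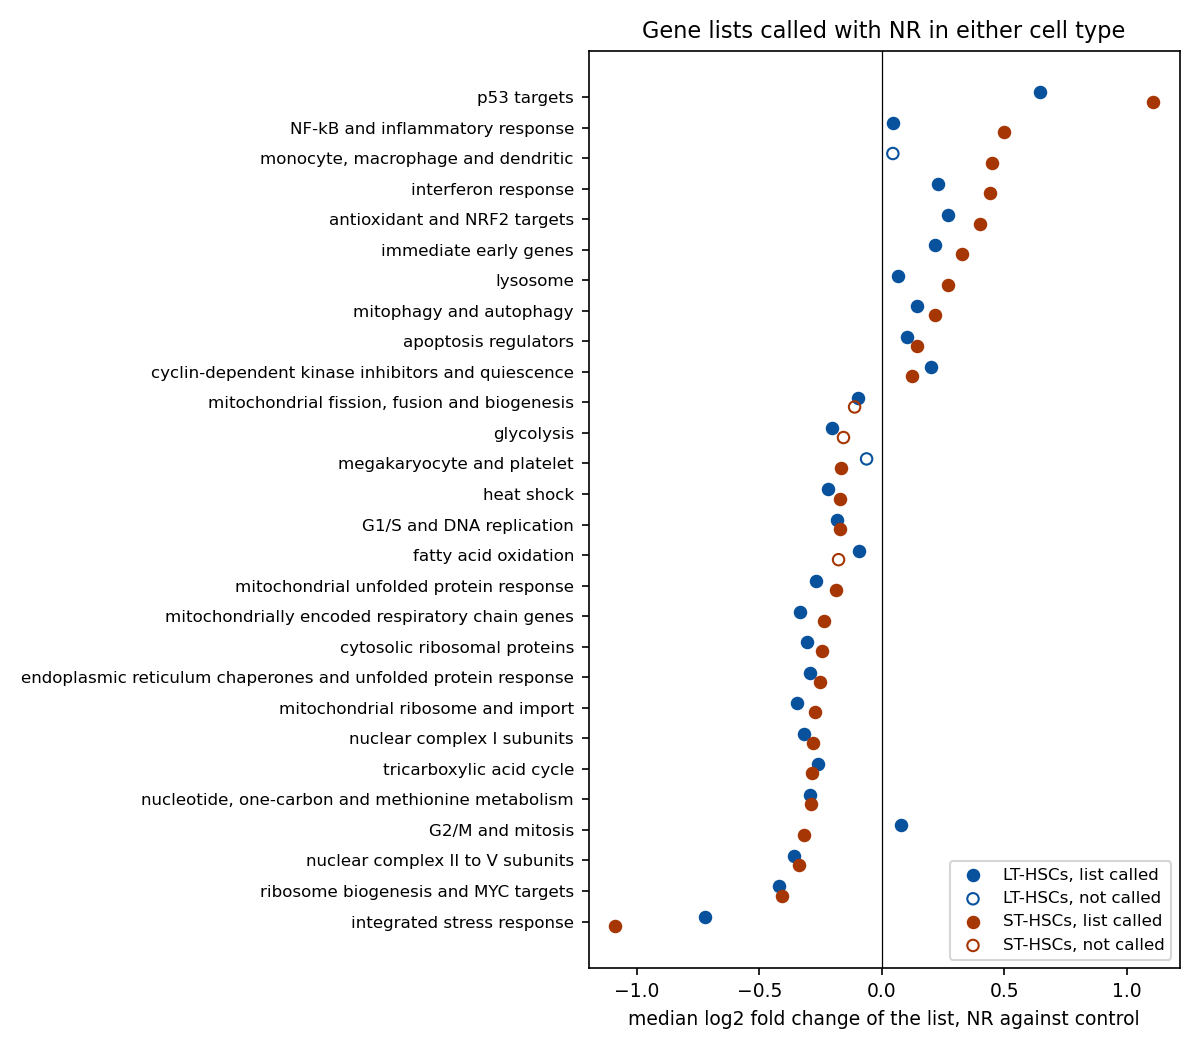
Median log2 change with NR (x axis) in LT-HSCs and ST-HSCs for each gene list called in either cell type (y axis); filled points mark a list call with the preset correlation, open points none. The p53 targets are farthest to the right (0.64 and 1.11) and the integrated stress response farthest to the left (-0.72 and -1.09).

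The difference of the NR effect, LT-HSCs minus ST-HSCs, tests whether the cell types respond differently. Only Cdkn1a (-1.28 ± 0.15, edgeR adjusted p = 0.023) and Phlda3 (-1.57 ± 0.21, adjusted p = 0.048) passed, so that both rose more in ST-HSCs. The next 3 genes by p did not pass: the actin-severing gelsolin gene Gsn (-0.81 ± 0.12, adjusted p = 0.078), the helicase gene Rtel1 (0.67 ± 0.10, adjusted p = 0.078) and the growth factor adaptor gene Grb10 (0.94 ± 0.14, adjusted p = 0.088). As a list, p53 targets differed in the same direction (median -0.47, list test adjusted p = 3.1e-17; adjusted p = 0.0697 with an estimated correlation), with 2 of 28 members lower and 15 adjusted over the list alone. Genes of the G2 phase and mitosis differed the other way (median 0.42, adjusted p = 6.5e-17, and adjusted p = 0.591 with an estimated correlation), with 0 members called by edgeR and 1 adjusted over the list alone. This list was called lower with NR in ST-HSCs but higher in LT-HSCs (median 0.077, list test adjusted p = 0.0065). In LT-HSCs 2 members were higher and 0 lower, and adjusted p was 0.742 with an estimated correlation. Monocyte markers (median -0.50, adjusted p = 0.0697 with an estimated correlation) and NF-kB genes (median -0.45, adjusted p = 0.095 with an estimated correlation) passed the list test with adjusted p = 3.9e-05 and 2.7e-07, with 0 members called by edgeR and 5 and 3 lower adjusted over the list alone. At an unadjusted p under 0.05 there were 1201 genes; DESeq2 called 136, limma-voom 5 and edgeR with the sample number as a replicate block 15. With the filter applied again, leaving out 1 library ended the call of Cdkn1a except for NR LT-HSC sample 2 and NR ST-HSC sample 3, and that of Phlda3 except for NR ST-HSC sample 3. The number of genes was 0 to 2 with the filter applied again and 0 to 17 with the same genes tested.

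Few genes of NAD metabolism passed. Of 24 tested genes, 0 rose and 2 fell in LT-HSCs and 2 rose and 1 fell in ST-HSCs, and the list passed in neither (adjusted p = 0.74 and 0.451). Naprt, which starts NAD synthesis from nicotinic acid, rose in ST-HSCs by 0.71 ± 0.12 (adjusted p = 0.0011) and by 0.45 ± 0.08 on average (adjusted p = 0.0012). The NR kinase gene Nmrk1 rose by 0.50 ± 0.11 on average (adjusted p = 0.0033). Its log2 change was 0.45 ± 0.15 in LT-HSCs (adjusted p = 0.08) and 0.56 ± 0.15 in ST-HSCs (adjusted p = 0.02), where with the same genes tested the call ended without control sample 1, control sample 3 or NR sample 1. The mitochondrial transhydrogenase gene Nnt fell by 0.37 ± 0.05 on average (adjusted p = 0.00023). Nampt, the rate-limiting gene of the nicotinamide salvage pathway, had a log2 change of -0.21 ± 0.07 on average (adjusted p = 0.051), and the mitochondrial deacetylase gene Sirt3 of 0.04 ± 0.05 (adjusted p = 0.67). Sirtuin and PARP genes, which use NAD, were higher in 1 and lower in 2 of 21 cases in LT-HSCs and 4 and 2 in ST-HSCs, and the list passed in neither (adjusted p = 0.522 and 0.146). With the filter applied again, the 4 higher in ST-HSCs became 1 without control sample 2, control sample 3 or NR sample 2. Without NR sample 1 the number was 0. Parp1, named after its values were seen, fell by 0.57 ± 0.05 on average, while the list as a whole had 6 members higher and 3 lower.

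LT-HSCs were compared with ST-HSCs in control culture to measure the difference between the sorted populations. Cd34 (ENSMUSG00000016494), the marker by which they were sorted, was at 259 ± 11.5 CPM in LT-HSCs and 627 ± 18.8 CPM in ST-HSCs (mean ± SD, n = 3), lower in LT-HSCs by -1.27 ± 0.07 on the log2 scale (SE; edgeR adjusted p = 5.5e-07). The Wnt modulator gene Sfrp1 was higher in LT-HSCs by 4.12 ± 0.28, the interferon-induced GTPase gene Gbp9 by 3.43 ± 0.28 and Clip3 by 3.31 ± 0.42. Tns2 was higher by 3.04 ± 0.17, Iigp1 by 2.69 ± 0.33, Ly6a, which encodes Sca1, by 2.59 ± 0.25, Tinagl1 by 2.55 ± 0.16 and Neo1 by 2.55 ± 0.33. Plac8 was lower by -2.98 ± 0.24, Tespa1 by -2.95 ± 0.21, Nlrc3 by -2.52 ± 0.21, the granzyme gene Gzmb by -2.48 ± 0.36, Igfbp7 by -2.22 ± 0.20 and Cd244a by -2.21 ± 0.11. Of the other sort markers, Slamf1 (CD150) was higher in LT-HSCs by 1.05 ± 0.14, Cd48 was lower by -2.60 ± 0.48 and Kit differed by 0.07 ± 0.06 (adjusted p = 0.75).

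A list of long-term HSC genes was higher in LT-HSCs in 21 and lower in 1 of 31 cases, or 24 and 1 adjusted over the list alone (median 0.79, adjusted p = 4.5e-25), and it passed with an estimated correlation (adjusted p = 0.0207). Sult1a1 was higher by 3.19 ± 0.26, the HSC reporter gene Fgd5 by 2.22 ± 0.18, Ctnnal1 by 0.85 ± 0.07 and Esam by 0.73 ± 0.07, while Itga2b, the 1 lower member, named after its values were seen, differed by -0.45 ± 0.11. Genes of multipotent progenitors and lymphoid priming were lower in 5 and higher in 2 of 17, or 6 and 4 adjusted over the list alone (median -1.28, adjusted p = 0.0161; adjusted p = 0.502 with an estimated correlation), a call that ended with the stricter filter. Of these, Cd52 was lower by -2.01 ± 0.26. Interferon response genes were higher in 11 and lower in 1 of 47, or 20 and 3 adjusted over the list alone (median 0.33, adjusted p = 2.4e-10; adjusted p = 0.638 with an estimated correlation). With any 1 of the 6 libraries left out 2 to 8 were higher with the filter applied again, and 4 to 7 with the same genes tested. In all, 696 genes were higher and 298 lower in LT-HSCs, and 108 to 137 were lower with any 1 of the 6 libraries left out and the filter applied again, 165 to 234 with the same genes tested. The number of higher genes was 458 without control LT-HSC sample 1, 406 without sample 2, 454 without control ST-HSC sample 2 and 440 without sample 3.

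With NR, LT-HSCs still differed from ST-HSCs in many of these genes. Sfrp1 was higher in LT-HSCs by 3.54 ± 0.26, Gbp9 by 3.47 ± 0.27, the RNA-binding protein gene Igf2bp2 by 2.93 ± 0.13, Evc2 by 2.80 ± 0.18, Tns2 by 2.65 ± 0.16, Clu by 2.56 ± 0.16 and Ly6a by 2.02 ± 0.24. Cd34 was lower by -1.54 ± 0.07 (edgeR adjusted p = 1.3e-07). Tespa1 was lower by -4.22 ± 0.23, Plac8 by -2.88 ± 0.25, Lat2 by -2.69 ± 0.14, Emilin2 by -2.45 ± 0.13 and Flt3 by -2.27 ± 0.20. The long-term HSC list was higher in 22 and lower in 0 of 31 cases, or 25 and 0 adjusted over the list alone (median 0.97, adjusted p = 3.1e-24; adjusted p = 0.0231 with an estimated correlation). Among these genes Vwf was higher by 2.31 ± 0.18, Mmrn1 by 1.16 ± 0.08 and Mecom by 0.97 ± 0.10. Here p53 targets were lower in LT-HSCs in 12 and higher in 1 of 28, or 17 and 2 adjusted over the list alone (median -0.34, adjusted p = 9.6e-08; adjusted p = 0.357 with an estimated correlation). Gadd45a was lower by -0.98 ± 0.14, Bbc3 by -0.76 ± 0.12 and Cdkn1a by -0.71 ± 0.10. With the filter applied again 4 of them were lower without NR ST-HSC sample 1, and 5 without NR ST-HSC sample 2, NR LT-HSC sample 1 or NR LT-HSC sample 3. In all, 753 genes were higher and 451 lower, a higher share of 62.5% that was 51.2% with the stricter filter. Between 375 and 681 were higher and 171 to 451 lower with any 1 of the 6 libraries left out and the filter applied again. The number lower was 242, 226 and 239 without NR LT-HSC samples 1, 2 and 3, and 171 and 199 without NR ST-HSC samples 1 and 2. The number higher was 414 and 375 without NR LT-HSC samples 1 and 2 and 486 without NR ST-HSC sample 1.

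**Figure D5:**
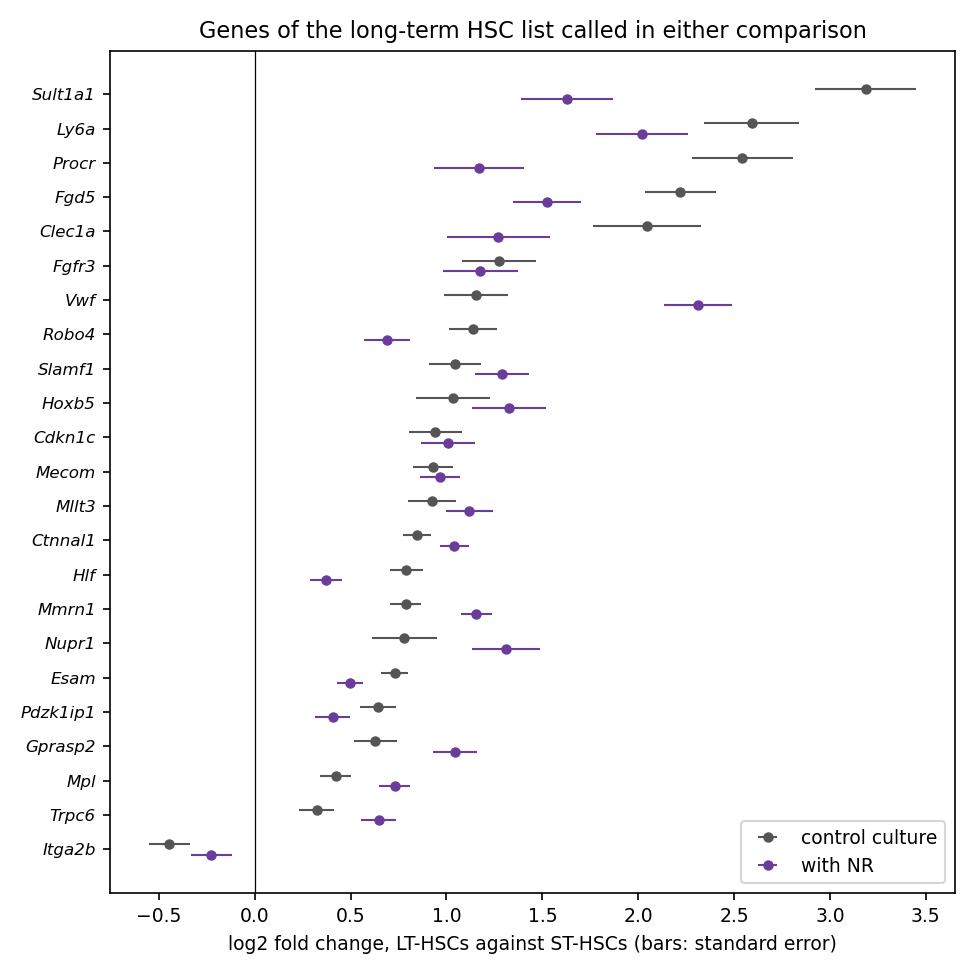
Log2 difference of LT-HSCs from ST-HSCs (x axis) for the genes of the long-term HSC list with adjusted p under 0.05 in either comparison (y axis), in control culture (grey) and with NR (purple); points are estimates and bars SE. In control culture 21 genes are higher in LT-HSCs, and with NR 22 are.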

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

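The tests of genes and lists in this part were planned. The explanations were chosen and tested after the result was seen, except those for the mitochondrial genes, whose predictions were written before their values.

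The share of reads in no annotated feature was 28.5% in NR LT-HSC sample 3 and 26.2% in NR ST-HSC sample 3, above every control library. Carry-over of genomic DNA would spread reads over the genome by length, so that reads in olfactory receptor exons (1106 genes, 3529 kb) would predict the unassigned reads with a slope near 1. The slope was 1.29 (SE 0.0499, r = 0.993), above 1 by more than its error. It counted as a match only within a wide range around 1 that was set after the data were seen. The intercept of 2.87 M reads was not predicted by olfactory receptor reads. Genomic DNA is therefore a candidate explanation for part of the unassigned reads. Unspliced RNA as the whole cause is excluded, since 77.6% of the rise was predicted from olfactory receptor reads alone. Both libraries are NR samples, while the other 4 NR libraries lay within the range of the controls.

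The NR effect on p53 target genes was smaller in LT-HSCs than in ST-HSCs, with a median difference of -0.47, Cdkn1a at -1.28 and Phlda3 at -1.57 (list adjusted p = 0.0697 with an estimated correlation). Without NR 4 members were higher in LT-HSCs and 1 lower (median 0.11, adjusted p = 0.0091, and adjusted p = 0.794 with an estimated correlation). With the filter applied again 2 were higher without control LT-HSC sample 1 and 2 without control LT-HSC sample 2. Such a higher level as the whole cause would leave equal levels with NR, but 12 members were then lower in LT-HSCs and 1 higher (list adjusted p = 0.357 with an estimated correlation). With the filter applied again 4 were lower without NR ST-HSC sample 1 and 5 without NR ST-HSC sample 2, NR LT-HSC sample 1 or NR LT-HSC sample 3, and with the same genes tested 7 to 10 were lower. The 2 libraries with the most unassigned reads as the whole cause are excluded, since the median was -0.52 without them. What sets the size of the rise in each cell type was not tested.

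Counts were near 0 for 5 mitochondrially encoded genes, which had at most 1 count in a library, although 8 others were counted. Reads shared with nuclear copies could explain genes that HTSeq would drop as multiply mapped: 99.5% of the 50-base stretches of mt-Atp6, 100% of mt-Co2, 99.9% of mt-Co3 and 98.8% of mt-Nd4l occur in other annotated transcripts. For mt-Atp8 the value was 0%, so this cannot tell, and the genome itself was not searched. Overlap with another mitochondrial gene as the whole cause is excluded, as it was 0% for mt-Co2. The falls of mitochondrially encoded genes therefore rest on 8 genes. Of these mt-Nd3, mt-Nd4 and mt-Co1 share 98.0%, 62.2% and 51.1% of their stretches and are uncertain.

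Libraries were also regrouped at random. The true grouping alone, 1 of 10 splits, gave as many called genes with NR in LT-HSCs (1975, at most 0 in others) and 1 of 10 in ST-HSCs (3348, at most 0). It was likewise 1 of 10 for the cell types in control culture (994, at most 0) and 1 of 10 with NR (1204, at most 1); 10 splits are too few for a share under 0.05. For the averaged effect it was 1 of 100 (4752, at most 1801), which excludes chance if the libraries of a cell type can be exchanged freely. With labels exchanged only within samples of the same cell type and number it was 1 of 32 (at most 265). If both cell types of a number had to be exchanged together, 4 arrangements would be left, too few for a share under 0.05. The split with 1801 sets the 3 libraries of each cell type with the lowest unassigned share against the other 3, which points to a structure of the samples that follows this background. For the difference of effects 5 of 100 splits gave at least 2 genes (2, at most 4752). All 4 others keep control and NR ST-HSCs apart and so count the NR effect itself, while the 90 splits that mix these libraries gave 0 in the edgeR test. The regrouping therefore cannot tell whether chance made the 2 genes.

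The median differences of the NR effect, LT-HSCs minus ST-HSCs, were as follows in the other lists that passed, each without a tested cause. None of them passed with an estimated correlation (adjusted p = 0.0697 to 0.916 with an estimated correlation). They were 0.42 for G2/M and mitosis, 0.22 for the integrated stress response and 0.13 for megakaryocyte and platelet genes. The megakaryocyte call ended with the sample number as a block (camera adjusted p = 0.0551). For monocyte, macrophage and dendritic markers the value was -0.50, for NF-kB genes -0.45, for immediate early genes -0.16, for lysosome genes -0.15, for NRF2 targets -0.13 and for interferon response genes -0.11. Apoptosis regulators had -0.0844, cytosolic ribosomal proteins -0.0740, mitochondrial ribosome and import genes -0.0493, mitophagy and autophagy genes -0.0460 and glycolysis genes -0.0421. For this difference the median was -0.0031 over the 10473 genes at 5 CPM or more and 0.339 over the 9357 below. Camera compares a list with all other genes, so lists with medians near 0 may pass as lower through the low-count genes.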

How the results depend on the processing

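Of the tests in this part, the unassigned-read covariate, the fits without 2 libraries and the fits with the same genes tested were chosen after results were seen. The main numbers of called genes (higher and lower) were 472 and 1503 with NR in LT-HSCs, 1155 and 2193 in ST-HSCs, 1563 and 3189 averaged, 2 for the difference of effects, and 696 and 298 in control culture and 753 and 451 with NR for LT-HSCs against ST-HSCs. Relative log expression factors gave 712 higher in LT-HSCs. Upper-quartile factors gave 829 higher in LT-HSCs, 1753 higher in ST-HSCs, 6 for the difference and 765 lower for the cell types with NR. The stricter filter gave 1261, 2003 and 2515 higher in LT-HSCs, ST-HSCs and averaged, 37 for the difference, and 505 and 899 lower for the cell types in control culture and with NR. Without a filter 944, 1321 and 2080 were lower and 43 differed. DESeq2 gave 1137, 2049 and 2574 higher, 136 for the difference, 1093 higher and 537 lower in control culture and 957 lower with NR. Limma-voom gave 5 for the difference and 1134 higher and 722 lower in control culture. The covariate gave 10 for the difference and 554 and 700 lower for the cell types. Without the 2 libraries richest in unassigned reads, 767 were higher and 738 lower in LT-HSCs, 1839 and 1165 in ST-HSCs and 2478 and 1842 averaged; with the same genes tested 877, 1229 and 2102 were lower. A fit of only the 2 groups gave 730 higher in LT-HSCs, 1105 higher and 509 lower for the cell types in control culture and 489 and 279 with NR; with the same genes tested, 1120 higher in control culture and 370 and 287 with NR.

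With the sample number as a replicate block 15 genes differed in their NR effect. No label pairs the samples. Correlations of same-numbered deviations ran from -0.23 to 0.84, with 10 of 12 over 0.1. Among them were all 3 for NR in LT-HSCs and all 3 for the cell types with NR. Of samples in other groups, the closest had the same number for 9 of 12 samples, a hint from the data only. The unassigned share also went with the number, being higher in sample 3 than in sample 1 of each group. The first principal component largely followed this share. These values therefore cannot tell pairing of the samples from shared background. With 1 library left out, the filter applied again and then the same genes tested, the numbers higher were 78 to 382 and 242 to 464 in LT-HSCs, 556 to 1326 and 833 to 1375 in ST-HSCs, 1093 to 1938 and 1273 to 1899 averaged, 406 to 643 and 470 to 566 for the cell types in control culture and 375 to 681 and 514 to 750 with NR. The numbers lower were 101 to 455 and 835 to 1082 in LT-HSCs, 398 to 759 and 1010 to 2130 in ST-HSCs, 1265 to 1764 and 2165 to 3156 averaged, 108 to 137 and 165 to 234 in control culture and 171 to 451 and 306 to 520 with NR; the difference had 0 to 2 and 0 to 17. The filter then kept 20217 to 22205 genes instead of 19830.

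Called lists numbered 26 in LT-HSCs, 25 in ST-HSCs, 24 averaged, 15 for the difference, 14 in control culture and 17 with NR. In this order an estimated correlation left 0, 1, 0, 0, 1 and 1, and with the covariate 2, 1, 2, 0, 1 and 1. Camera with the sample number as a block kept 112 of the list calls of all comparisons and ended 9. The directional fry test gave 17 in LT-HSCs, 26 in ST-HSCs, 27 averaged, 1 for the difference, and 4 and 5 for the cell types. The mixed fry test gave 38 in ST-HSCs, 38 averaged, 7 for the difference, and 25 and 31 for the cell types; the stricter filter gave 9 in control culture. With 1 library left out, the filter applied again and then the same genes tested, these were 19 to 24 and 20 to 24, 21 to 26 and 21 to 27, 21 to 25 and 22 to 25, 9 to 27 and 10 to 24, 9 to 14 and 11 to 13, and 8 to 22 and 8 to 22. Signs were compared for the named genes only, and among these only genes without a call changed sign. Sirt3 in LT-HSCs (-0.0267) was 0.0246 with relative log expression factors, 0.0204 with upper-quartile factors, 0.0207 without a filter, 0.0378 with the stricter filter and 0.00813 with the covariate. It was 0.108 without the 2 libraries, 0.0707 so with the same genes tested, 0.0237 with only 2 groups and 0.0249 with DESeq2. With 1 library left out it ran from -0.0788 to 0.113, and from -0.0608 to 0.0525 with the same genes tested. Nampt in ST-HSCs ran from -0.200 to 0.0148, the last without control sample 1, and Rpl10a in control culture from -0.164 to 0.00804, the last without control ST-HSC sample 1. Kit with NR was -0.0176 with only 2 groups and the same genes tested, and -0.0924 to 0.0810 with 1 library left out.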

Other observations

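The tests in this part were planned, but the genes picked out here were chosen after the result was seen.

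Of the averaged NR effects of the lists in this paragraph 0 passed with an estimated correlation and 6 with the preset correlation. Regulators of apoptosis rose in 8 and fell in 2 of 25 cases on average (adjusted p = 0.281 with an estimated correlation), immediate early genes in 11 and 2 of 26 (0.281), and cyclin-dependent kinase inhibitors and quiescence genes in 9 and 3 of 27 (0.281), with Btg2 at 1.02 ± 0.11 and Rbl2 at 0.55 ± 0.07. Heat shock genes fell in 10 of 14 cases (adjusted p = 0.362 with an estimated correlation), mitochondrial fission, fusion and biogenesis genes in 6 of 22 (0.281) and fatty acid oxidation genes in 9 of 20 (0.571), where 1 rose. As lists, 3 others did not pass for the averaged effect: glycolysis genes (5 higher and 9 lower of 19), hypoxia response genes (4 and 8 of 23) and cholesterol synthesis genes (7 and 6 of 34). In ST-HSCs long-term HSC genes did not pass as a list either (9 higher and 9 lower of 31). Of these genes Procr rose by 2.11 ± 0.26 and Fgd5 by 0.94 ± 0.18, while Vwf fell by 2.23 ± 0.17 and Slamf1 by 0.65 ± 0.14. As lists, 5 more passed neither in LT-HSCs, nor in ST-HSCs, nor for the averaged effect, whose counts are given here: erythroid genes (1 higher and 4 lower of 18), myeloid and neutrophil genes (1 and 3 of 22), mast cell and basophil genes (0 and 1 of 15), lymphocyte genes (0 and 1 of 13) and endothelial and stromal genes (0 and 3 of 17). Outside the lists, the mitochondrial ribosomal RNA genes mt-Rnr1 (0.71 ± 0.19) and mt-Rnr2 (0.51 ± 0.10) rose with NR in ST-HSCs, where the share of counts from mitochondrial genes was highest in NR sample 1 (0.833%).

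An estimated correlation left 0 of 24 averaged list calls. With the unassigned-read covariate as well, p53 targets (camera adjusted p = 0.0443) and ribosome biogenesis genes (camera adjusted p = 0.049) passed. The other averaged camera calls rest on the preset correlation. The directional fry test, which presets no correlation, gave 27 averaged lists. It asks whether the members of a list change at all, while camera compares them with the other genes. With 4752 of 19830 genes called for the averaged effect, the fry number cannot back the camera calls. RNA alone cannot separate an effect of NR on the cells from a change in which cells survived 2 days of culture. NAD, protein levels and cell function were not analysed here.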
